A study of Mus musculus with 6 samples.

How the data were processed

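The deposited table holds 1 value per probe set for each of 6 Affymetrix Mouse Gene 1.0 ST arrays, 3 of dendritic cells from recipients of naive-donor marrow and 3 from recipients of UV-donor marrow. The values are log2 signals, per the range of the deposited values, which run from 2.52 to 14.6 with nearly equal array medians. RMA, which corrects background, normalizes arrays by quantiles and summarises probes, is named in the submitters' processing notes together with the packages oligo and limma, with no versions. The notes used here do not say at which summary level RMA was run. Quantiles of the deposited arrays were not identical. RMA equalises probe quantiles before summarising, so array differences in spread can remain in the summarised values. No scan date or hybridisation batch is given in the sources used here, so batches could not be examined. Implantation of prostaglandin E2 pellets is mentioned in the design text, and samples of that treatment were not analysed here.

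Every array was assigned to its group and replicate number through its labels. No table column of other samples was present. The values were used as deposited, with no further normalization. Gene names came from the platform annotation, matched by Entrez identifier to a RefSeq gene table of the mouse assembly GRCm38.p6, used for names only. Of 35556 probe sets, 21789 had 1 gene symbol, 1621 had several and 12146 were not listed. Of those with 1 symbol, 21698 were matched by identifier and 0 symbols changed. Probe sets with several symbols or none were left out of the gene test. The 1-symbol probe sets covered 19938 genes, of which 999 had more than 1 probe set, and the probe set with the highest mean over all 6 arrays stood for each. Genes with a mean below the 30th percentile were left out as dim, leaving 13956. The number of arrays limits the precision.

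Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, UV-donor minus naive-donor, two-sided). P-values were adjusted by Benjamini-Hochberg over all tested genes, and an adjusted p under 0.05 was a call. The 18 process lists and 13 marker lists, written down before the data were examined, were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted within each kind of list. Beside it stand camera with an estimated correlation and fry, whose main p asks whether the genes of a list move on balance 1 way without comparing them with other genes. With an estimated correlation 0 process lists and 0 marker lists were called. An exact permutation test of 3 arrays against 3 cannot give a two-sided p below 0.1, so the calls rest on limma's sharing of variance across genes. Figures were drawn with matplotlib 3.10.9.

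Genes named in the text were chosen by a rule fixed before the data were examined. It took, per direction, up to 12 called genes with the largest log2 difference and non-overlapping groups, filled where fewer passed with genes of smallest p that had non-overlapping groups and a difference of at least 0.5, skipping predicted genes and small RNAs. It added the 3 members of smallest p of each process list, the 2 of each marker list, and a fixed set of genes of glycolysis, dendritic cells and prostaglandin E2. Haao was put in that set because the study is known to have followed it, so its choice was not blind to the study. Haao is also a member of the kynurenine list, so tests of that list were not blind either. Genes named outside the rule are identified as such.

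The tests were tried on simulated data with the means of the 13956 genes of this comparison and their variances as moderated by limma. Each of 10 draws had 200 changed genes. Of genes changed by 0.3 on the log2 scale, 66.9% were recovered, and of those changed by 0.6, 99.0%. False calls made up 6.56% of all calls. These simulated arrays had no correlation between genes, and their variances were those limma had drawn towards a common value. They state the power in that simpler case. A list raised by 0.3 was called in 10 of 10 draws.

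Alternatives planned before the data were examined were the replicate number as a block, other filters on dim genes, centred medians, cyclic loess, quantile normalization, an intensity trend with a robust prior, array weights, the mean of a gene's probe sets, all probe sets, other thresholds, other list tests and leaving out each array in turn. Quantile normalization of the list tests was added after the data were seen.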

Results

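The study asked whether ultraviolet (UV) irradiation of skin leaves a lasting mark on dendritic cells that later grow from bone marrow, and its title concerns glycolysis in such cells. Recipient C57BL/6J mice had been injected with 2000000 bone marrow cells from a congenic donor strain, B6.SJL-Ptprca, which carries the CD45.1 form of the leukocyte antigen CD45. The donors were either naive or had been exposed on shaved dorsal skin to up to 8 kJ/m2 of broadband UV radiation. Marrow of the recipients was cultured for 5 days with the growth factors GM-CSF and IL-4, each at 10 ng/ml, which drives marrow cells towards dendritic cells. Cells carrying CD11c, the integrin used to define dendritic cells, were then enriched to above 95% with magnetic beads. RNA of 3 preparations per group was hybridised to whole-transcript expression arrays, giving 6 arrays in all. The labels do not say that the preparations came from separate recipients, so the p-values below measure only the spread between these preparations, which may be technical.

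The 6 arrays were closely alike. Pearson correlations over all 35556 probe sets ran from 0.995 to 0.997 within groups and from 0.995 to 0.996 between groups. Array medians lay between 7.16 and 7.23 on the log2 scale. The interquartile range of the signals was wider on each UV-donor array (3.71 to 3.75) than on each naive-donor array (3.61 to 3.68). The first principal component of the tested genes held 48.6% of the variance and placed the 3 UV-donor arrays at 14.1, 4.31 and 3.79, and the 3 naive-donor arrays at -9.41, -2.01 and -10.8. UV-donor replicate 1 therefore stood farthest from the naive-donor arrays.

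CD11c-enriched preparations from recipients of UV-donor marrow had higher signals for a small set of genes. Which cells in the preparations carried these transcripts was not tested. The largest rises were in Klrb1f, which encodes a C-type lectin receptor, at 2.25-fold, and in Ms4a3, a gene of granulocyte and monocyte progenitors, at 2.13-fold. Stfa2, a cysteine protease inhibitor of the stefin family, rose 1.85-fold, the decoy interleukin-1 receptor Il1r2 rose 1.70-fold, and the calcium-binding protein S100a8 rose 1.70-fold. Haao, the enzyme of the kynurenine pathway that makes the quinolinic acid precursor, rose 1.34-fold. No gene passed the test in the lower direction.

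Of 13956 tested genes, 24 were higher and 0 lower in the UV-donor group at an adjusted p under 0.05 (limma, two-sided, Benjamini-Hochberg). At an unadjusted p under 0.05 limma gave 1340 higher and 766 lower genes. All 24 called genes had non-overlapping groups, as had 3038 of all tested genes, or 21.8%. The average over all splits of 3 arrays against 3 is 10%. Genes vary together, so a single split can lie above that average, and the share was not computed for the other splits. Folds of the 24 called genes ran from 1.29 to 2.25 and 2 of them reached 2-fold. The count moved with single arrays: it was 1 without naive-donor replicate 1, 3 without naive-donor replicate 3, 1 without UV-donor replicate 2 and 1 without UV-donor replicate 3. It was 32 without naive-donor replicate 2, with 17 of the 24 among them, and 22 without UV-donor replicate 1, with 16 of the 24. It was 0 when all 35556 probe sets were tested together.

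Klrb1f (probe set 10542140) had a log2 signal of 9.18 ± 0.07 in the naive-donor group and 10.35 ± 0.30 in the UV-donor group (SD, n = 3 each), a difference of 1.17 (SE 0.13, limma adjusted p = 0.0199). Ms4a3 (probe set 10466224) went from 6.97 ± 0.06 to 8.07 ± 0.34, a difference of 1.09 (SE 0.14, limma adjusted p = 0.0387). Haao (probe set 10453260) went from 10.55 ± 0.05 to 10.97 ± 0.02, a difference of 0.42 (95% interval 0.31 to 0.53, limma adjusted p = 0.0199). With single arrays left out, the Haao difference stayed between 0.40 and 0.45 while its limma adjusted p ran from 0.042 to 0.134. It passed only without naive-donor replicate 2, and its call was lost without any 1 of the other 5 arrays.

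The remaining called genes named by size were Sectm1a (log2 difference 0.77), Cd209e (0.75), Ifitm1 (0.74), Asb2 (0.72), P2ry13 (0.70), Cdca7 (0.65) and Prkcq (0.64). Cd209e encodes a lectin of the DC-SIGN family, Ifitm1 an interferon-inducible membrane protein, P2ry13 a receptor for ADP and Prkcq protein kinase C theta. Haao, Cd209a, C1qb and Ltf were called too and are given with their lists below. Another 8 called genes lay outside the naming rule and are named here after their values were seen. These were Fgf23 (0.64), Rab27a (0.61), Ifitm6 (0.59), Il2ra (0.57), Cyp4f16 (0.50), Ccr4 (0.49), Jaml (0.45) and Tnfaip8l3 (0.36). Several called genes belong to families of closely related copies (Cd209, Ifitm, Stfa, Klrb1), whose probe sets were not checked here for shared sequence.

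In the lower direction 5 genes met the rule for genes that did not pass, and none of them is a call. Car6, a secreted carbonic anhydrase, differed by -1.39 (SE 0.22, limma adjusted p = 0.0638), and Cd5l, a macrophage-secreted scavenger protein, by -0.996 (SE 0.16, limma adjusted p = 0.0627). The differences of Lyve1 (-0.54), Cox6a2 (-0.70) and Phyhd1 (-0.67) had limma adjusted p-values from 0.163 to 0.197.

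**Figure D1:**
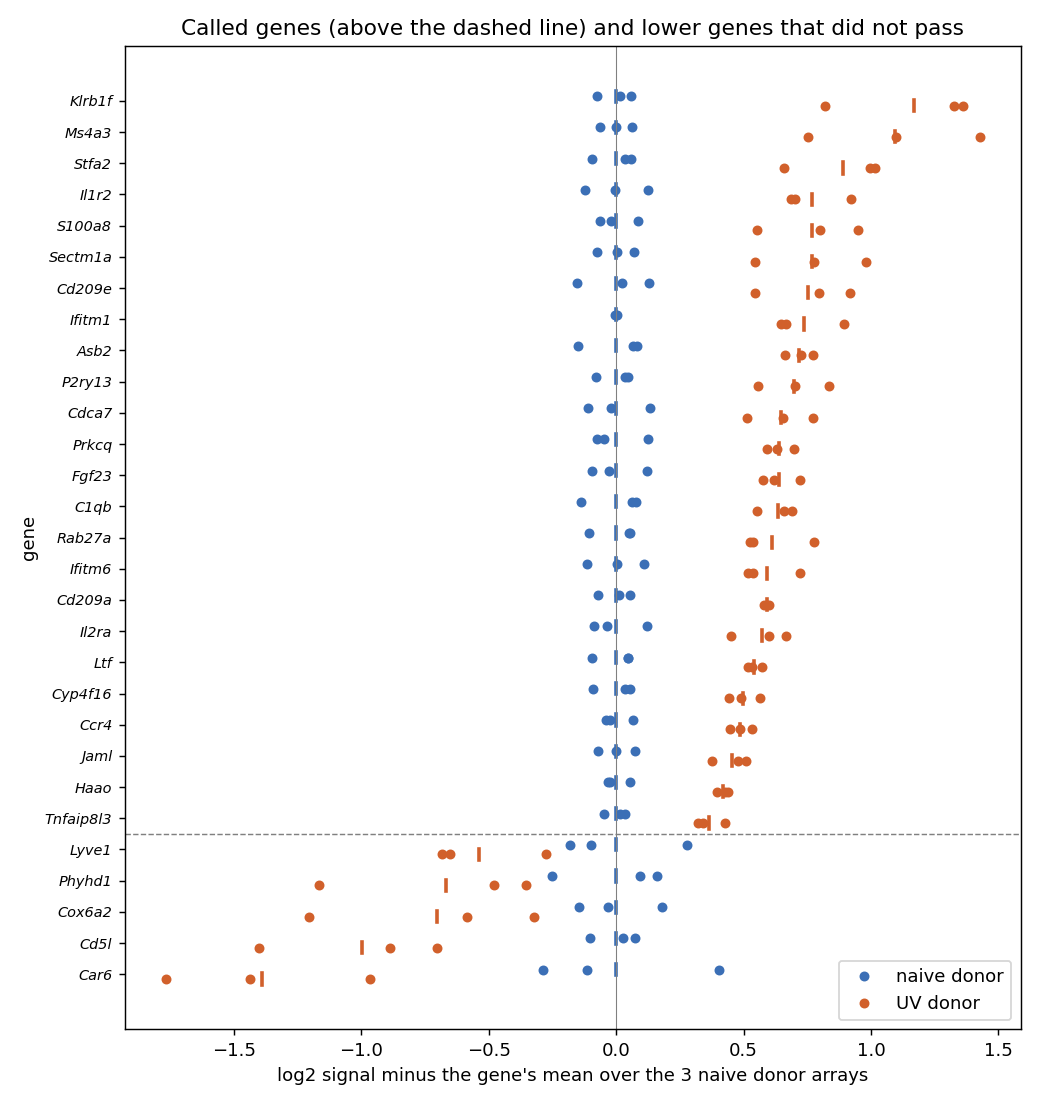
Log2 signal of each array minus the gene's mean over the 3 naive-donor arrays (horizontal axis) for the 24 called genes, above the dashed line, and the 5 lower genes that did not pass, below it. Points are arrays, blue for naive donors and orange for UV donors, and short bars are group means. The 3 UV-donor points lie above the 3 naive-donor points in all 24 called genes.

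The title's question concerns glycolysis. The arrays measured transcripts and not glycolytic activity, and the transcripts of glycolysis showed no called shift as a group. Of 22 tested genes of glycolysis and lactate export, 11 had higher and 11 lower values in the UV-donor group, with a mean log2 difference of 0.016 (camera adjusted p = 0.948). None was called, over all genes or adjusted over the list alone. The glucose transporter Slc2a1 differed by -0.026 (95% interval -0.14 to 0.090), hexokinase Hk2 by -0.052 (-0.20 to 0.10), pyruvate kinase Pkm by 0.012 (-0.11 to 0.13), lactate dehydrogenase Ldha by 0.0065 (-0.10 to 0.11) and the lactate exporter Slc16a3 by 0.037 (-0.092 to 0.17). The members with the smallest p were the glucose transporter Slc2a3 (0.35), the lactate transporter Slc16a1 (-0.28) and the aldolase Aldoc (0.16), with limma adjusted p-values from 0.215 to 0.299.

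The kynurenine and NAD synthesis list held the called gene Haao. Of its 17 tested genes, 9 had higher values, 1 was called over all genes and 2 adjusted over the list alone. The second was Kmo, kynurenine monooxygenase, which acts upstream of Haao, with a difference of 0.69 (SE 0.11) and a limma adjusted p of 0.0627 over all genes. Wars, which loads tryptophan onto its transfer RNA, differed by -0.21. The list did not pass camera (mean 0.090, adjusted p = 0.421). Fry, which asks whether the genes move on balance in 1 direction, gave an adjusted p of 0.0411. The median of the list was 0.011, with 8 genes lower in value. Haao was known to be followed by the study when the list was written, so these tests were not blind to it.

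Genes of cell division and of cholesterol synthesis had the largest mean shifts among the 18 process lists. All 31 tested proliferation genes had higher values in the UV-donor group, with a mean log2 difference of 0.51, or 1.43-fold. Examples are the mitotic kinase Aurka (0.53), the spindle protein Prc1 (0.62) and the anaphase activator Cdc20 (0.52). Of these genes 0 were called by limma over all genes, 29 were higher at an unadjusted p under 0.05, and 29 were called adjusted over the list alone. Camera with a preset correlation of 0.01 called the list (adjusted p = 1.5e-19), but the call was lost (adjusted p = 0.68 with an estimated correlation), the members' estimated correlation being 0.90. The list mean was 0.81 on UV-donor replicate 1 and 0.38 and 0.36 on the other UV-donor arrays, while the naive-donor arrays ran from -0.13 to 0.22.

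All 19 tested genes of cholesterol synthesis and SREBP2 targets also had higher values, with a mean of 0.34, or 1.27-fold. Cyp51, lanosterol demethylase, differed by 0.81 (SE 0.17), the mevalonate pathway kinase Pmvk by 0.33 and the sterol reductase Tm7sf2 by 0.26. Limma called 0 of them over all genes, with 14 higher at an unadjusted p under 0.05, and 12 were called adjusted over the list alone. Camera called the list (adjusted p = 1.59e-10), and not when correlation was estimated (adjusted p = 0.68 with an estimated correlation). Here too UV-donor replicate 1 was highest, at 0.58, against 0.28 and 0.17 on the other UV-donor arrays and -0.05 to 0.07 on the naive-donor arrays.

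Dendritic cell maturation genes shifted slightly. Of 24 tested genes 20 had higher values, with a mean of 0.098 (camera adjusted p = 0.00646, but adjusted p = 0.68 with an estimated correlation). Without naive-donor replicate 2 the camera adjusted p was 0.0611. None was called over all genes and 1 was called adjusted over the list alone. The ligand of the costimulator ICOS, Icosl, differed by 0.20, the OX40 ligand Tnfsf4 by 0.35 and the actin bundler Fscn1 by 0.41. The costimulatory molecules Cd80 (0.11) and Cd86 (0.078) and the homing receptor Ccr7 (0.043) did not pass.

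**Figure D2:**
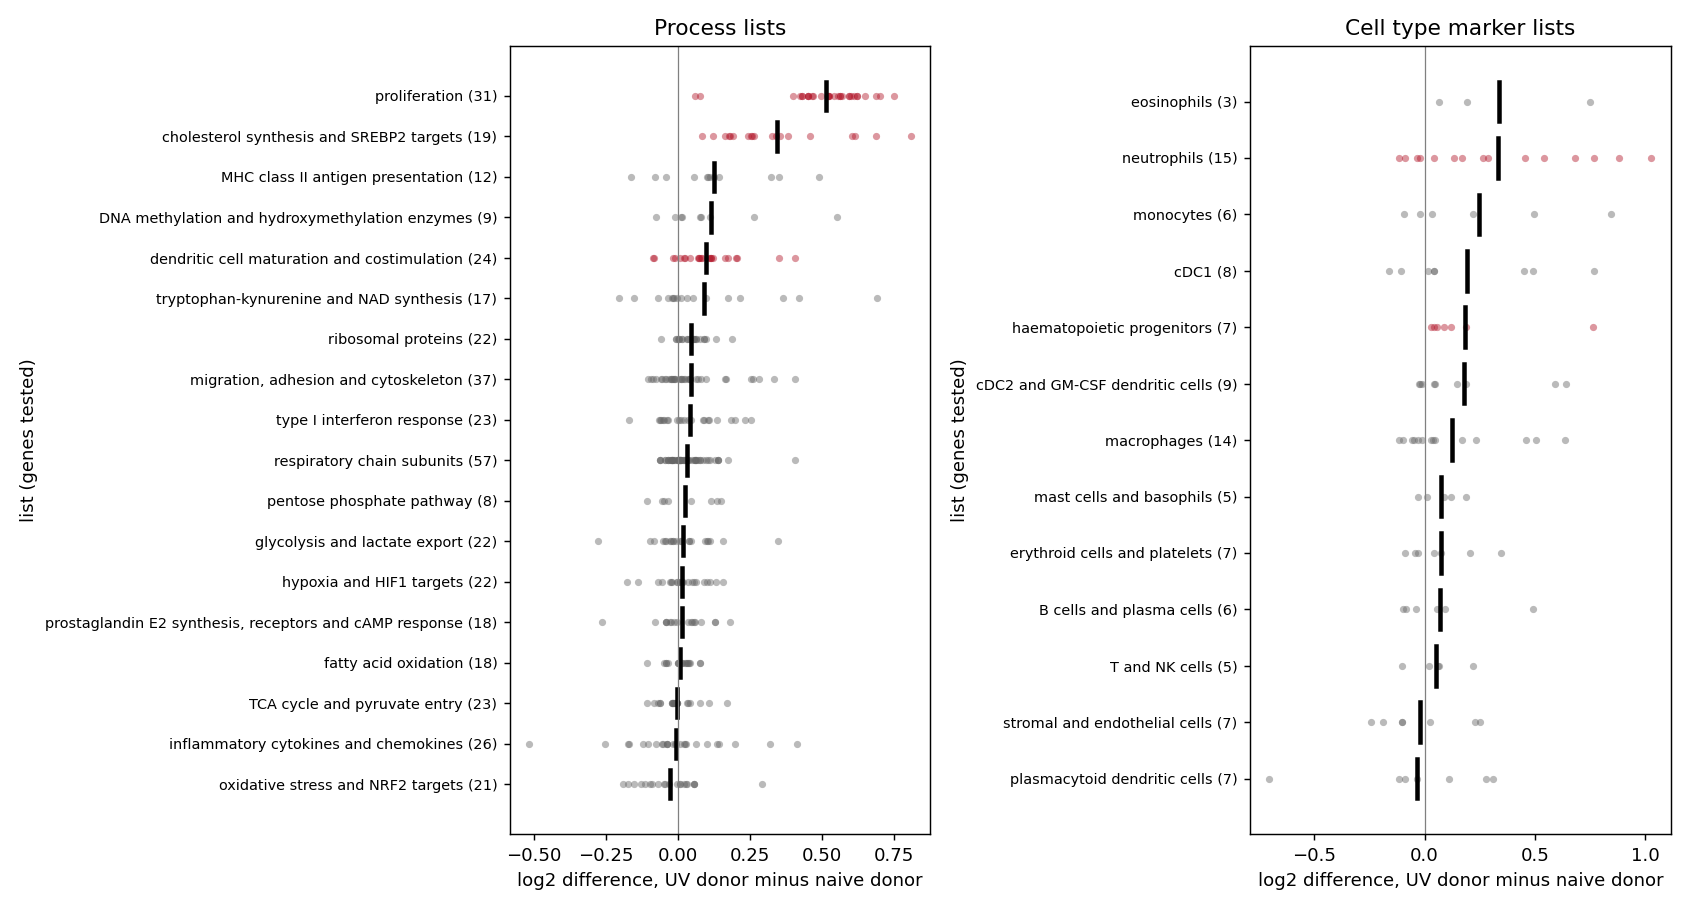
Log2 difference between UV-donor and naive-donor arrays of every tested member (points) of the 18 process lists (left) and 13 marker lists (right), with the number tested in brackets and the list mean as a black bar. Red marks lists called by camera with the preset correlation. Proliferation (mean 0.51) and cholesterol synthesis (0.34) lie to the right of the other process lists.

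Camera called none of the other 13 process lists either. For antigen presentation on MHC class II, 9 of 12 tested genes had higher values (mean 0.13, adjusted p = 0.0709), with Ciita, the class II transactivator, at 0.49, H2-Ob at 0.32 and Lgmn at -0.16, and with 1 gene called adjusted over the list alone. H2-Ab1 differed by 0.10. Inflammatory cytokines and chemokines went both ways, 11 higher and 15 lower of 26 (mean -0.0088, adjusted p = 0.948). Cxcl2 (0.41), Tnf (0.32) and Il1b (0.20) were the 3 called adjusted over that list alone, and Cxcl2 had a limma adjusted p of 0.0686 over all genes. Of 37 migration and adhesion genes 21 had higher values (adjusted p = 0.418), with the gelatinases Mmp9 (0.33) and Mmp2 (0.26) and the integrin Itgal (0.16) leading and 1 called adjusted over the list alone. The oxidative stress list (mean -0.028, adjusted p = 0.288) had 1 gene called adjusted over the list alone. Its leading members were Osgin1 (0.29), Gclm (-0.19) and Srxn1 (-0.13).

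In the lists of mitochondrial and carbon metabolism no gene was called, over all genes or adjusted over the list alone. The tricarboxylic acid cycle had an adjusted p of 0.784, led by Pdk3 (0.17), Fh1 (0.11) and Dlst (-0.11). The respiratory chain had an adjusted p of 0.345, with 36 of 57 genes higher in value, led by Ndufa1 (0.40), Uqcrh (0.14) and Atp5e (0.17). The pentose phosphate pathway had an adjusted p of 0.948, led by Tkt (0.11), H6pd (-0.11) and Prps1 (0.15). Fatty acid oxidation had an adjusted p of 0.978, led by Cpt1a (-0.11), Etfdh (0.077) and Acaa1a (0.076). Hypoxia and HIF1 targets had an adjusted p of 0.948, with Hif1a itself at -0.14, Kdm3a at 0.13 and P4ha2 at -0.18.

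The remaining process lists likewise held no gene called over all genes or adjusted over the list alone. Prostaglandin E2 genes were split 9 to 9 (adjusted p = 0.948), with the receptors Ptger2 (-0.26) and Ptger4 (0.13), the synthase Ptgs2 (-0.043), Pde4b (0.13) and Nr4a3 (0.18). Type I interferon response genes had an adjusted p of 0.421, led by Isg20 (0.25), Dhx58 (0.20) and Bst2 (0.11). DNA methylation enzymes had an adjusted p of 0.286, led by Dnmt1 (0.26), Uhrf1 (0.55) and Mbd2 (0.11). Ribosomal protein genes had an adjusted p of 0.137, with Rpl14 at 0.19, Rps14 at 0.097 and Rps25 at 0.075.

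Among the 13 lists of cell type markers, neutrophil markers had the smallest camera p. Of 15 tested markers 11 had higher values (mean 0.33, camera adjusted p = 0.000108, but adjusted p = 0.26 with an estimated correlation). S100a8 (0.77) and lactoferrin, Ltf (0.54), were called over all genes, and 8 markers were called adjusted over the list alone. Fry gave the list an adjusted p of 0.0278. The list mean ran from 0.23 to 0.39 on the UV-donor arrays and from -0.05 to 0.09 on the naive-donor arrays.

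All 7 tested markers of haematopoietic progenitors had higher values (mean 0.18, camera adjusted p = 0.0464, but adjusted p = 0.26 with an estimated correlation). Cd34 led with 0.76 (SE 0.16) and was the 1 marker called adjusted over the list alone, followed by the transcription factor Gata2 (0.12). Camera did not call this list without naive-donor replicate 3 (adjusted p = 0.0942), UV-donor replicate 1 (0.0736) or UV-donor replicate 2 (0.095).

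Dendritic cell and macrophage markers included called genes without a camera call of their lists. Cd209a, a lectin of dendritic cells grown with GM-CSF, rose by 0.59 (SE 0.05, limma adjusted p = 0.0199), and the related Cd209d differed by 0.64 without passing. Their list had a camera adjusted p of 0.0659 and a fry adjusted p of 0.0278, and 2 markers were called adjusted over the list alone. In the macrophage list the complement gene C1qb rose by 0.63 (SE 0.07, limma adjusted p = 0.0199) and Adgre1, a macrophage surface receptor, differed by 0.51 (limma adjusted p = 0.0627). That list had a camera adjusted p of 0.101 and a fry adjusted p of 0.0278, with 3 markers called adjusted over the list alone.

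The other marker lists held no gene called over all genes. Adjusted over the list alone, 2 markers were higher for cDC1, 1 for eosinophils, 2 higher and 1 lower for plasmacytoid cells, 1 higher and 1 lower for stromal and endothelial cells, and none for the rest. Camera gave adjusted p-values of 0.0602 for eosinophils (Prg2 0.75, Siglecf 0.19), 0.454 for cDC1 (Wdfy4 0.45, Itgae 0.77), 0.289 for monocytes (F13a1 0.50, Ms4a6c 0.84) and 0.289 for mast cells and basophils (Kit 0.19, Gata2 0.12). It gave 0.742 for B cells and plasma cells (Fcrla 0.49, Igll1 0.095), 0.742 for T and NK cells (Gzmb 0.22, Il7r -0.10), 0.53 for erythroid cells and platelets (Pf4 0.21, Ppbp 0.34) and 0.454 for stromal and endothelial cells (Pecam1 0.23, Col3a1 -0.19). Plasmacytoid markers (Spib 0.31, Cox6a2 -0.70) had an adjusted p of 0.781. Their mean was -0.036 and their median -0.035, while camera's direction was upward. The enriched antigen itself, Itgax (CD11c), differed by -0.044 (95% interval -0.14 to 0.057), and Ptprc, which encodes CD45, by 0.034 (-0.078 to 0.15).

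**Figure D3:**
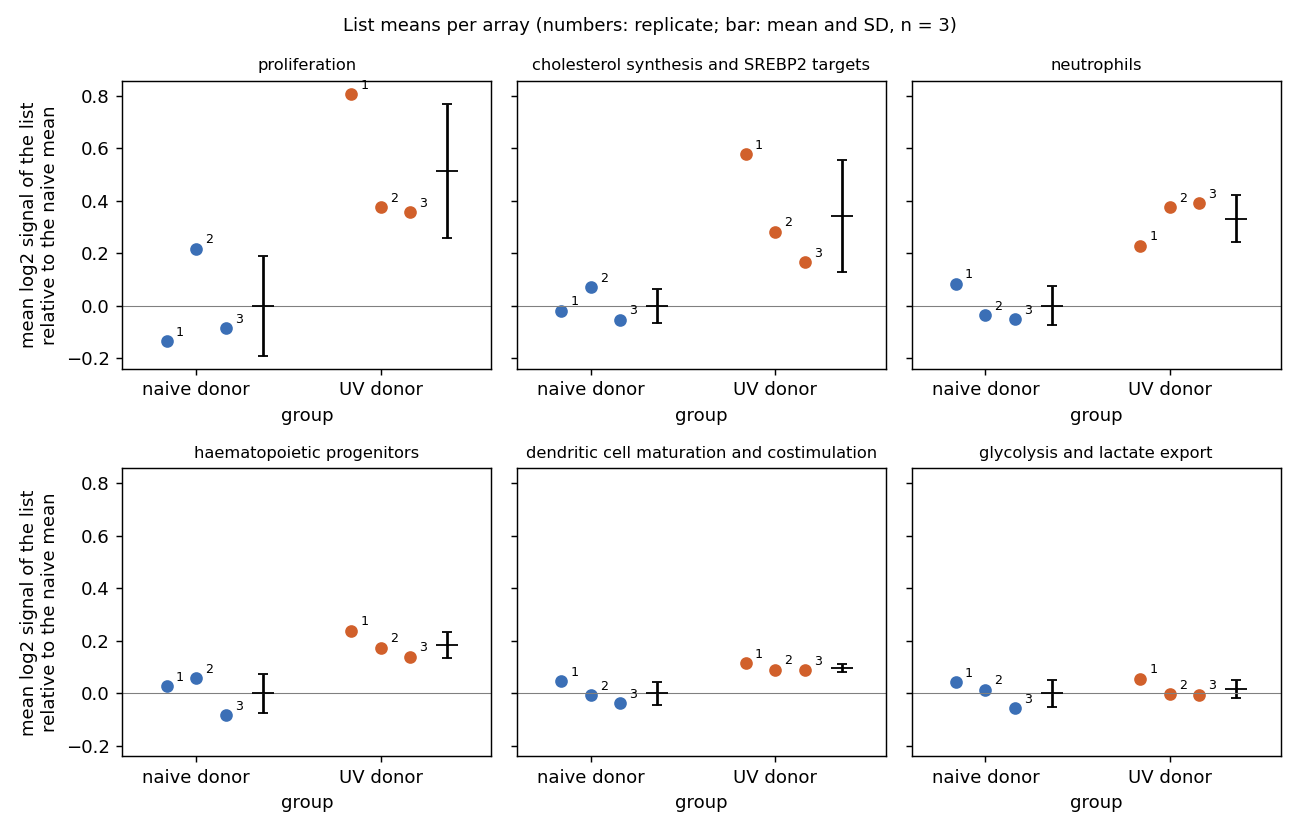
Mean log2 signal of 6 lists on each array, relative to each gene's naive-donor mean, for naive-donor (blue) and UV-donor (orange) arrays. Numbers are replicates and black bars are mean and SD (n = 3). UV-donor replicate 1 is highest for proliferation (0.81) and cholesterol synthesis (0.58), and the groups overlap for glycolysis.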

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

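The count of 24 genes moved with the processing. It was 43 with centred array medians, which raised the median difference of all tested genes to 0.036, 43 with array weights (39 higher, 4 lower) and 45 with an intensity trend and robust prior (42 higher, 3 lower). Each of these included all 24 genes. At an adjusted p under 0.10 it was 70, at an unadjusted p under 0.05 it was 2106, and 94 of those were at least 1.5-fold. With all probe sets tested it was 0 (limma, 1801 higher and 1708 lower at an unadjusted p under 0.05). Leaving out single arrays gave 1 to 32. The cyclic loess, quantile and other filter counts ran from 23 to 26.

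The replicate numbers were shared by both groups but did not pair the arrays. Deviations from the group means of same-numbered arrays correlated at -0.13, -0.22 and 0.15. With the replicate block limma called 0 genes (1286 higher and 666 lower at an unadjusted p under 0.05), while camera called 3 process lists and 3 marker lists.

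The process lists called numbered 3, and 5 with no dim filter or with cyclic loess, 1 with fry, 0 with an estimated correlation and 2 to 5 with single arrays left out. Marker lists called numbered 2, and 5 with no dim filter, 4 with quantile normalization, 1 each with the 50th percentile filter, centred medians or ranks, 0 with an estimated correlation and 1 to 4 with single arrays left out. The estimated correlation ended the calls of proliferation (mean 0.51), cholesterol synthesis (0.34), maturation (0.098), neutrophils (0.33) and progenitors (0.18). Fry did not call the same lists apart from neutrophils, with means of 0.51, 0.34, 0.098 and 0.18, and called kynurenine and NAD synthesis (0.090). The progenitor list was also lost with centred medians (0.22), ranks (0.18) and the 50th percentile filter (0.43, a mean over the fewer markers left by that filter). With single arrays left out its mean ran from 0.14 to 0.21, and that of the maturation list from 0.078 to 0.12. The glycolysis list, never called, turned direction in camera under the 50th percentile filter (mean 0.016), and its mean ran from -0.012 to 0.038 with single arrays left out.

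Among named genes only values near 0 changed sign: Pkm was -0.012 with the mean of its probe sets, Slc2a1 0.0081 with centred medians and Ptgs2 0.0033 with cyclic loess. With single arrays left out Pkm ran from -0.026 to 0.038, Slc2a1 from -0.056 to 0.0066, Ldha from -0.014 to 0.019, Slc16a3 from -0.0058 to 0.065 and Ccr7 from -0.0074 to 0.10. Where no construction is named, the cause was not tested. The table holds no detection values, so signal over background could not be used to bound dim genes.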

Other observations

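Leaving out UV-donor replicate 1 and testing the lists with an estimated correlation were planned before any expression value was seen. The reading of the former as a test of that array, and the other tests in this part, were chosen after the result they concern was seen. The bound of the range tests was also changed more than once after values were seen. Its last change moved the olfactory receptors and the proliferation and cholesterol lists from open to short of the whole. Grouping the tested genes by the stem of their symbols gave 580 families of at least 4 genes, and camera with the preset correlation called 22 of them, 11 lower. With quantile normalization it called 14, of which 4 were lower, and cyclic loess gave the same counts. The replication helicase family Mcm (10 genes, 1 of them lower in value, mean log2 difference 0.37), the Cdca family (7 genes, 0 lower, 0.40), the kinesins (35 genes, 11 lower, 0.23) and the Gimap GTPases of lymphoid cells (6 genes, 0 lower, 0.27) were higher as families. Several Mcm and kinesin genes are members of the proliferation list, so these families are not separate from that result. The lower families called with the deposited values and with quantile normalization were the microRNA genes (92 genes, 84 of them lower), the olfactory receptors (65 genes, 59 lower), the collagens (42 genes, 40 lower) and the keratin-associated proteins (16 genes, all lower). Their mean log2 signals were 7.74, 7.10, 7.59 and 7.71 in that order. The higher families named had 9.06 (Mcm), 9.07 (Cdca), 8.41 (kinesins) and 7.76 (Gimap). Whether signal near background underlies the lower shifts was not tested. The direction of each family named here was the same with centred medians, cyclic loess and quantile normalization. No family was called by camera with an estimated correlation (0 of 580, adjusted p = 0.891 for each family named here, with unadjusted p from 0.00469 for the keratin-associated proteins to 0.111 for Cdca).

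The 11 lower families differed by a mean of -0.099 (SE between arrays 0.015, 305 genes). The wider signal range of the UV-donor arrays was examined as their source, since quantile normalization, which equalises the range, moved the median difference from -0.056 to -0.016 in the third signal decile of all 19938 genes and from 0.044 to 0.0029 in the seventh. Quantile normalization removed -0.016 of the mean of the 11 families (95% limit between arrays -0.049), short of the whole. The 11 families were picked as lower in these same values, and the set includes the 4 families described next. The part removed therefore cannot decide whether the range is the whole cause for that set. The part removed was -0.0054 of -0.099 for the microRNA genes (limit -0.035) and -0.029 of -0.112 for the olfactory receptors (limit -0.067). It was -0.0078 of -0.084 for the collagens (limit -0.040) and -0.0061 of -0.145 for the keratin-associated proteins (limit -0.035). These 4 families were picked because they stayed called after quantile normalization, so the small parts removed were largely set beforehand and decide nothing. The olfactory receptors kept a mean of -0.083 with a 95% interval between arrays of -0.184 to 0.018, so its sign stays open. The 7 families whose calls ended went from -0.087 (SE 0.0089) to -0.064 (SE 0.017, 95% interval -0.112 to -0.016), a smaller mean with a wider spread, and for them too the part removed, -0.023 (limit -0.058), was short of the whole. No biological explanation was tested for these families, and none of them is called with an estimated correlation.

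The higher proliferation and cholesterol lists were examined for the same range effect and for 1 unusual array. With the deposited values the means were 0.51 and 0.34, and the highest mean of 10000 random lists of like signal was 0.15 and 0.16. The random lists were matched on signal only, while members of these lists varied together (estimated correlation 0.90 and 0.74). Random lists therefore understate how far such a list can move, and the comparison decides nothing about the donors. Quantile normalization removed 0.028 of each (95% limit between arrays 0.046), leaving 0.49 (SE 0.18, adjusted p = 1.5e-21 by camera with the preset correlation) and 0.31 (SE 0.13, adjusted p = 9.4e-11), which argues against the range as the whole cause, though neither list is called with an estimated correlation. Without UV-donor replicate 1 the cholesterol mean was 0.22. Both other UV-donor arrays (lowest 0.17) lay above the highest naive-donor array (0.071) by more than the naive SD of 0.064. This argues against UV-donor replicate 1 as the whole cause, though the cut rests on few arrays and was set after the values were seen. For proliferation the mean without that array was 0.37. The gap between 0.36 and 0.22 was smaller than the naive SD of 0.19, so this stays open. A larger share of immature marrow cells may also raise division genes: 1 of 7 progenitor markers was higher adjusted over the list alone, with a list median of 0.090, which leaves it open together with an effect of the donor's irradiation.

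Neutrophil markers were examined for carried-over cells, which selection for CD11c would largely remove. The members' mean pairwise correlation of deviations within groups was 0.10, at the 96.0th percentile of 10000 random lists of like signal. Carried-over neutrophils would give this, but so could genes regulated together within the dendritic cells, so it does not tell them apart. Named after their values were seen, Ngp differed by 1.03, Ly6g by 0.88 and S100a9 by 0.68, none passing over all genes. Lcn2 differed by only 0.13, from a naive-donor level of 11.32. Of the 15 markers 11 had higher and 4 lower values. None of the 15 markers is in another list, and how many of them the dendritic cells themselves express was not tested. A few neutrophils in the UV-donor preparations and a change within the dendritic cells both remain possible, and the donor's irradiation was not separated from either. The same holds for the called genes S100a8 and Ltf, which are members of that list.

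The 6 arrays make 10 splits of 3 against 3, too few for a share under 0.05. The real split called 24 genes and the highest other split 0, so 1 of 10 splits gave as many. For process lists 7 of 10 splits gave as many calls as the real 3, and the highest other gave 4. For marker lists 2 of 10 splits gave as many as the real 2, and the highest other gave 2. The 21600 probe sets not used in the gene test gave 0 calls by limma among themselves, with 630 higher and 954 lower at an unadjusted p under 0.05.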
